A study of Mus musculus with 2 samples.

How the data were processed

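Chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody to H3K27ac was done on whole stomachs of mouse embryos at embryonic day 15.5, in 2 replicates from separate pools of 78 and 62 embryos of both sexes, with a fragment size range of 300 to 500 bp per the labels. The 4 lists of peaks used here are deposited in the narrowPeak format on assembly mm10. Each replicate has a list called on its own reads and a control, the pooled list was called on the reads of both replicates and a control, and the replicated list is described as derived from the pooled list and both replicate lists. The aligner, caller and versions are not given in the sources used here, nor is the rule that makes a peak replicated. The fold of each peak is the ratio of ChIP signal over control that the authors' caller gave, and it is deposited on a linear scale. The −log10 p and −log10 q of each peak are also deposited as the authors' caller gave them. These values were used to describe, rank or filter peaks within a list, since the depths of the libraries are unknown, and were compared between lists only in a test of depth in the closing part. A possible control is named in the labels but was not analysed here. All peaks of the 4 lists had an authors' p under 0.01, and each list also held peaks with an authors' q above 0.01.

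Peaks on the 21 assembled chromosomes were used. Intervals of a list that overlapped each other were merged for the Jaccard index, promoter domains, clusters and motif controls, while peaks were counted unmerged. The covered length of the replicate lists was the same either way, 60.9 Mb in replicate 1 and 42.0 Mb in replicate 2. Genes came from GENCODE release M21 and sequence from the GRCm38.p6 reference, the build that mm10 names. Promoter windows reached 1 kb to both sides of the 54327 transcription start sites of 21911 protein-coding genes. A peak of a list was counted as shared where a peak of the other list covered at least 50% of either of them, and the base-pair Jaccard index divided the sequence covered in both lists by that covered in either. For the expectation under chance the replicate 2 peaks were placed at random 100 times within their chromosomes. A gene's acetylated stretch, or promoter domain, was the longest run of peaks, joined over gaps of at most 1 kb, that overlapped any of its promoter windows. Peaks outside promoter windows (distal peaks) were joined over gaps of at most 12 kb into clusters, and clusters with at least 10 kb covered by peaks were counted as large. Distal peaks include those of a promoter domain that lie outside the windows.

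There was 1 group of 2 replicates, so no test between groups and no test across replicates could be made. The tests run over genes or peaks and describe these lists. The 29 gene lists, which hold 440 distinct matched genes, and their tests were chosen at the outset. The share of each list with a replicated promoter peak was compared with all other protein-coding genes by two-sided Fisher's exact tests, and with 10000 random lists matched in 10 strata of the ratio of observed to expected CpG in the promoter window by a two-sided permutation test. That ratio was taken in the window of each gene's outermost start site, while a peak at any start site counted. The lists were thus not matched on other start sites or on their number. Odds ratios of lists and motifs were computed after a small constant was added to each count. Where all genes of a list had a peak, the odds ratio is finite only for this reason, and its size follows the length of the list. The median length of promoter domains was compared with 10000 random lists of the same size among genes with a replicated promoter peak. Medians of a single replicate given beside it cover the same genes. Genes with no promoter peak in that replicate counted as having no length and were not left out. Genes with a promoter peak in 1 replicate only were compared between the replicates by two-sided exact binomial tests at the ratio found over all genes. Of the list symbols, 2 non-coding genes, H19 and Meg3, were not among the protein-coding genes and are described apart. Consensus motifs of 19 factor families were sought on both strands in the middle 500 bp of distal peaks and in control windows of the same chromosome outside all pooled peaks, matched in GC content in steps of 2 percentage points. The window had this size whatever the width of the peak, so in narrower peaks it also held sequence beside the peak. The median width of distal peaks was 531 bp in the replicated list, 286 bp in replicate 1 and 256 bp in replicate 2. A control was found for 44647 of 44666 distal peaks, and Fisher's exact test compared the shares. The reversed, not complemented, consensus was counted beside each motif as a match of equal base composition, although reversal can create or remove a CpG. All p-values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05.

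The named genes were chosen by a rule. It took the 3 members of each list with the longest promoter domain and the first 2 members, in list order, without a replicated promoter peak. To these it added the genes of the 20 longest promoter domains, the 5 strongest genes with a promoter peak in 1 replicate only for each replicate, the 10 largest distal clusters and the 10 strongest replicated peaks. Genes named beside these, such as single members of a list with 1 peak and the genes in the closing part on other families, were chosen after their values were seen.

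The results fixed before the data were examined were computed again under the alternatives that apply to each. These were other overlaps (1 bp, or 50% of both peaks), the authors' q of at most 0.01 or fold of at least 4, the 20000 strongest peaks, peaks joined first, promoter windows of 500 and 2500 bp, the outermost start site only, other joining distances (none or 3 kb for promoters, 5 and 20 kb for clusters), motif windows of 200 and 1000 bp or controls 5 kb downstream, and each replicate list alone in place of the replicated list, which stands for leaving out the other replicate. The densities per chromosome, gene families, non-coding genes and lists near clusters were computed with the main settings only. Leaving out the X and Y chromosomes and counting each domain once per list were added after seeing the data. Wilson intervals at the 95% level were given for shares of peaks. Because no counts of reads were in the files, no interval or lower limit that rests on sequencing depth could be given.

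The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with bedtools 2.31.1 and samtools 1.23.1. They were tested on simulated data. Of 4149 interval values 0 differed from a base-by-base calculation. Simulated gene lists with odds raised 20 times were called in 82.7% of 300 cases and with odds lowered 20 times in 95.3%, and unchanged lists in 1.07%. All unchanged genes had the same chance of a peak in that simulation, so the last rate does not cover the effect of promoter CpG. Domains made 3 times longer were called in 100% of 20 lists and unchanged ones in 0.855%. All 19 motifs were recovered when placed in 20% of windows of random sequence, and 0 were called when none was placed. Those windows were neither genomic nor matched in GC content, and the share was above the differences found in the peaks. They therefore do not give the rate of false calls in the real comparison. Lists of 20 genes with a peak in 1 replicate only, more than any list tested here held, were called in 98.5% of 200 cases when 95% of them were in replicate 1 against 60% of other genes, and in 2.5% when unchanged. Peaks on unplaced sequence were left out of all comparisons because their position in the genome is not known.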

Results

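Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in whole stomachs of mouse embryos of the B6NCrl strain at embryonic day 15.5. There was 1 group of 2 replicates, each from its own pool of male and female embryos, 78 in replicate 1 and 62 in replicate 2. The deposited files held 1 list of peaks for each replicate, a list called on both replicates together (the pooled list) and a list of peaks that the authors classed as replicated. Replicate 1 had 116396 peaks covering 60.9 Mb, and replicate 2 had 94387 peaks covering 42.0 Mb. The pooled list had 117349 peaks covering 66.6 Mb, of which the replicated list held 61818, covering 52.7 Mb or 1.93% of the genome. The files used here held no read counts, so the depth of each library is unknown and no level of acetylation could be compared between libraries. All positions are on mouse genome build mm10. The labels state no purpose beyond profiling this mark in this tissue.

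The first comparison asked which regions carried the mark in both pools of embryos. The longest acetylated stretch at a promoter in the replicated list covered Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6, homeobox genes that give cells their position along the body axis, and the longest stretch over them was 57.3 kb in replicate 1 and 37.7 kb in replicate 2. The promoter of Foxf1, a forkhead gene of the gut mesenchyme, lay in a stretch of 21.7 kb in replicate 1 and 13.7 kb in replicate 2. That of Col1a1, which encodes a chain of type I collagen, lay in a stretch of 27.8 kb and 20.0 kb, respectively. Among protein-coding genes, 12086 had a promoter peak in both replicates, 913 in replicate 1 only and 393 in replicate 2 only, so that 90.2% of the genes with a promoter peak in either replicate had it in both.

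Sharing was also counted over all peaks, promoter peaks included. This follows another rule than the count of genes above, so the shares cannot be set against each other. Of the replicate 1 peaks, 44.8% (52186; 95% Wilson interval 44.5 to 45.1%) were found in replicate 2, counted as shared where a peak of either list was covered by 50% or more. Of the replicate 2 peaks, 65.4% (61704; 65.1 to 65.7%) were found in replicate 1. The intervals cover counting error over peaks only. Both lists covered 32.2 Mb in common, which was 52.9% of the sequence covered in replicate 1 and 76.7% of that covered in replicate 2, a base-pair Jaccard index of 0.456. In 100 random placements of the replicate 2 peaks within their chromosomes, the highest index was 0.0113 and at most 2.84% of replicate 1 peaks were found. Peaks with a weak enrichment over the control, by the authors' fold within each list, were the ones found least. Of the decile of replicate 1 peaks with the lowest fold, 12.7% were found in replicate 2, against 99.9% of the decile with the highest. The median fold of replicate 1 peaks was 4.44 where they were found in replicate 2 and 2.89 where they were not, with median widths of 579 and 236 bp. With a fold of at least 4 in both lists, 64.6% of replicate 1 peaks and 84.2% of replicate 2 peaks were shared, and with 50% of both peaks required, 29.5% and 36.4% were.

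**Figure D1:**
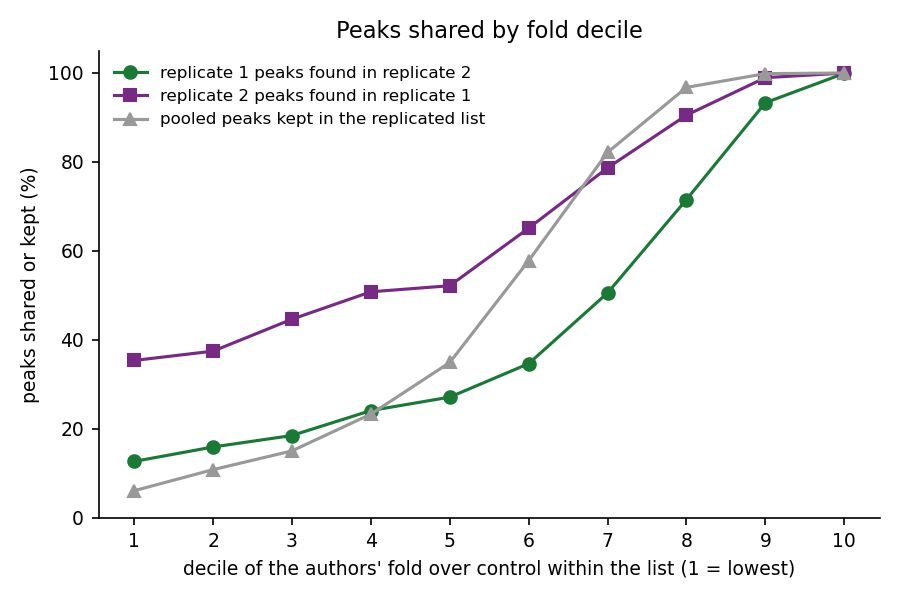
Share of peaks found in the other list (vertical axis, %) by decile of the authors' fold within each list (horizontal axis, 1 is the weakest decile), with a line for replicate 1 peaks found in replicate 2, for replicate 2 peaks found in replicate 1 and for pooled peaks kept in the replicated list. Each line rises with the fold, for replicate 1 from 12.7% in the weakest decile to 99.9% in the strongest.

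Of the genes with a promoter peak in replicate 1 alone the strongest, by the authors' fold there, were Rap2b (15.9), a RAS-related GTPase, Vpreb1 (14.3), a surrogate light chain of the pre-B-cell receptor, Dnah2 (10.3), an axonemal dynein, Frrs1 (8.69) and Slc10a5 (7.11). Of those with a peak in replicate 2 alone they were Slc35g3 (22.2), Ppp1r27 (15.5), Ghdc (6.24), Dusp14 (5.08) and Ddx47 (4.57), an RNA helicase. For Rap2b, Vpreb1, Dnah2, Frrs1, Slc35g3 and Ppp1r27 the other replicate had a peak whose edge lay 1.03 to 1.25 kb from the transcription start site, just outside the window of 1 kb. For Ghdc the nearest peak of the other replicate was 27.9 kb away, for Ddx47 5.88 kb, for Slc10a5 4.27 kb and for Dusp14 2.66 kb. The gene lists fixed for this tissue held few such genes. In two-sided exact binomial tests of the 16 lists with at least 1 such gene, adjusted by Benjamini-Hochberg, 0 passed, with a smallest adjusted p of 0.963 and 0 lists at an unadjusted p under 0.05. The WNT and BMP list had 1 such gene in replicate 1 and 3 in replicate 2, and the squamous forestomach list had 4 and 1. No list held more than 5 such genes, and even with all of them in replicate 1 the smallest unadjusted exact p would be 0.323, so no list could have passed towards replicate 1.

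A further comparison asked what the authors' replication step kept. The replicated list held promoter peaks of Foxa1, Foxf1 and Barx1, for example, and the peaks left out of it were mostly weak. Of the pooled peaks, 52.7% (61818; 95% Wilson interval 52.4 to 53.0%) were in the replicated list, with 79.0% of the covered sequence. The median fold in the pooled list was 3.89 for peaks that were kept and 2.51 for those that were not. Of the decile with the lowest fold, 6.10% were kept, and of the decile with the highest, 100%. Of the replicated peaks, 97.9% matched a peak of replicate 1, 86.8% a peak of replicate 2 and 84.9% both, so overlap with both of the deposited replicate lists, as counted here, was not the authors' rule. The promoter of Ghdc, for example, was in the replicated list with no promoter peak in replicate 1.

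The next comparison asked where in the genome the mark lay. The strongest of the replicated peaks, by the authors' fold over the control in the pooled data, lay 3.94 kb from the start of Sirt4 (chromosome 5, 115488661 to 115491024) with a fold of 53.4. The next were at the promoters of Zfp143, an activator of housekeeping genes (49.8), Sp3, a GC-box-binding factor (49.7), Arid1a, a subunit of the BAF chromatin remodelling complex (48.0), and Klf7, a Krüppel-like factor (43.8). A peak 5.49 kb from Zfp869 (42.8), the promoter of Tnrc18 (42.7), a peak in the promoter window of Sp1, 0.388 kb from its start (42.2), and the promoters of Myl12a (42.2) and Nfib (41.7) completed the 10 strongest. Peaks that overlapped a window of 1 kb on both sides of a protein-coding transcription start site made up 27.7% of the replicated list (17152 of 61818), in windows that filled 2.37% of the genome. That share was 19.2% in the replicate 1 list and 23.0% in the replicate 2 list. By the middle of the peak, 42.4% of all replicated peaks lay in introns, 24.5% between genes and 5.34% in exons. The median fold was 6.26 at promoters and 3.58 elsewhere, and the median width was 818 and 531 bp. With only the outermost start site of each gene the promoter share was 22.9%, and among peaks with a fold of at least 4 it was 44.2%. The share of the replicated list was above that of either replicate list, so it describes the list and not the libraries.

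A replicated peak lay at the promoter of 12212 of 21911 protein-coding genes (55.7%), compared with 12999 in replicate 1 and 12479 in replicate 2. Whether a gene had such a peak followed the CpG content of its promoter closely. In the decile of genes with the lowest ratio of observed to expected CpG, taken at the outermost start site, the share was 4.47%, and in the decile with the highest it was 93.3%. For this reason each gene list was compared both with all other genes and with random lists matched on that ratio.

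The main question was which gene lists, drawn up for tissues of the stomach wall, carried the mark at their promoters. Whole stomachs were used, so a peak cannot be assigned to a tissue, and some lists share genes or stretches. Genes of the gastric foregut epithelium had a promoter peak in 19 of 20 cases. The longest acetylated stretches among them were at Krt19, a keratin of simple epithelia (15.9 kb), Foxa1, a forkhead factor that opens chromatin in endoderm (15.7 kb, but 8.52 kb in replicate 2), and Elf3, an epithelial ETS factor (13.4 kb, but 4.90 kb in replicate 2), and Foxq1 had no replicated peak. Genes of the gastric mesenchyme and its regional regulators had a peak in 19 of 20 cases too, with the longest stretches at Foxf1 (16.2 kb), the hedgehog receptor gene Ptch1 (12.8 kb, but 25.7 kb in replicate 1) and Barx1, a homeobox gene of the stomach mesenchyme (12.6 kb). Hand1 had none. All 16 smooth muscle genes had a peak, with stretches of 11.3 kb at Tpm1 (tropomyosin), 5.27 kb at Srf, the factor that binds the CArG box, and 5.14 kb at Mylk (myosin light chain kinase). So did all 16 genes of fibroblasts and extracellular matrix, with 20.2 kb at Col1a1, 6.83 kb at Pdgfra and 6.04 kb at Pdgfrb.

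In contrast, the secreted and ion-transport products of differentiated gastric cells were almost without the mark. Of 16 such genes only Gkn3, a gastrokine, had a replicated promoter peak, of 0.288 kb, and Atp4a and Atp4b, the subunits of the acid-secreting proton pump, had none. The replicate 1 list had a peak at 5 of these genes and the replicate 2 list at 3. Without replicate 2 the odds ratio was 0.328 and the list no longer passed. Markers of the squamous forestomach had a peak at 10 of 14 genes in the replicated list and at 13 of 14 in replicate 1. The longest were at Krt15 (15.9 kb, in the same stretch as Krt19), Pitx1, a homeobox gene of hindlimb, pituitary and oral epithelium (14.4 kb), and Grhl3 (13.1 kb). Trp63, the regulator of stratified epithelia, and Krt4 had none in the replicated list. Of the intestinal epithelium list 6 of 14 genes had a peak, with stretches at Lgals4 (3.39 kb), Satb2 (1.26 kb) and Vil1 (1.06 kb), and none at Cdx1 and Fabp2.

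These counts were tested by two-sided Fisher's exact tests against all other protein-coding genes, adjusted over the 29 lists. The odds ratio was 10.3 for the gastric epithelium (adjusted exact p = 0.000486) and 10.3 for the gastric mesenchyme (adjusted exact p = 0.000486). It was 26.2 for smooth muscle and 26.2 for fibroblasts and matrix (adjusted exact p = 0.000479 for each), and 0.0767 for the differentiated gastric products (adjusted exact p = 0.000265). For smooth muscle and fibroblasts, with a peak at every gene, the odds ratio is finite only through the constant added to each count. The squamous forestomach (odds ratio 1.85, adjusted exact p = 0.365) and the intestinal epithelium (adjusted p = 0.490) did not pass, although the squamous list did in replicate 1 alone (odds ratio 6.18 without replicate 2). Against lists matched on promoter CpG, the gastric epithelium (median of matched lists 60%, adjusted permutation p = 0.00193), smooth muscle (56.2%, adjusted p = 0.00145) and fibroblast lists (50%, adjusted p = 0.00145) still passed. The mesenchyme list (median 75%, adjusted permutation p = 0.133) and the differentiated gastric products (median 18.8%, adjusted p = 0.386) did not. Genes within a list are not replicates, so these p-values describe the lists of peaks from these 2 libraries and not a population of embryos.

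**Figure D2:**
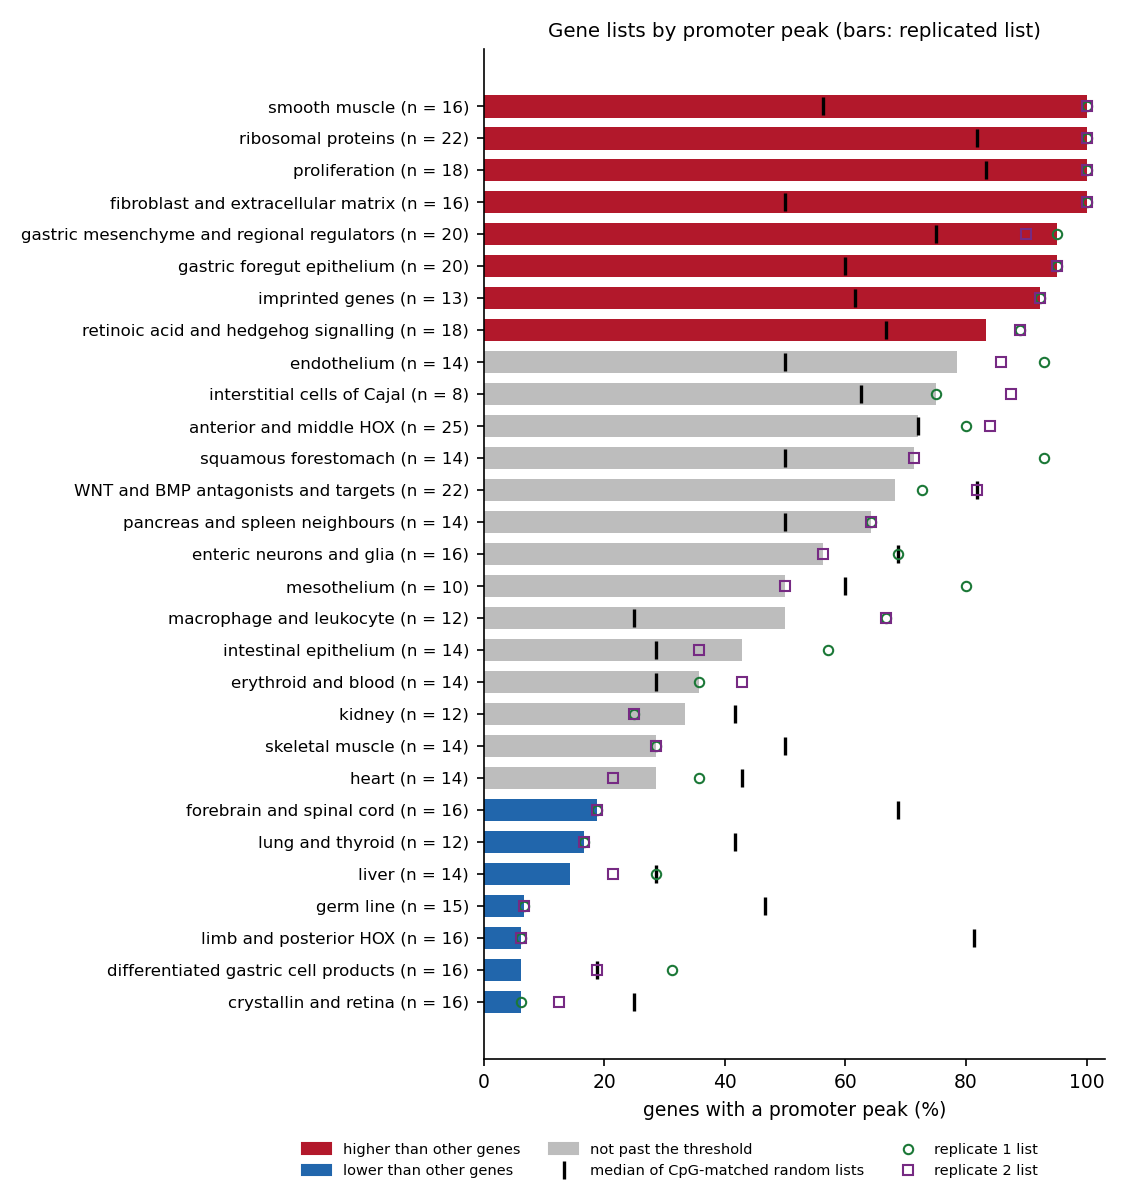
Share of the genes of each list with a promoter peak (horizontal axis, %), with bars for the replicated list coloured by the test against all other genes, open circles and squares for the replicate 1 and replicate 2 lists, and black ticks for the median of random lists matched on promoter CpG. Smooth muscle stands at 100% against a matched median of 56.2%, and limb and posterior HOX at 6.25% against 81.2%.

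The gene lists of other cell types of the stomach wall had a promoter peak at part of their genes, beside 55.7% of all protein-coding genes. In whole stomachs a peak at such a gene cannot be assigned to that cell type. Enteric neurons and glia had a peak at 9 of 16 genes, with the longest stretches at Hand2 (10.4 kb), a basic helix-loop-helix gene that also serves the gut mesenchyme, the neuregulin receptor gene Erbb3 (7.55 kb) and Gfra1 (2.79 kb), and none at Phox2a or Ret. Interstitial cells of Cajal, the pacemakers of the gut, had a peak at 6 of 8 genes, with 5.21 kb at Kcnj8, 3.92 kb at Ano1 and 3.85 kb at Etv1, and none at Hcn4 and Thbs4. Endothelium had 11 of 14, with 6.63 kb at Egfl7, 3.47 kb at Esam and 2.03 kb at Eng, and none at Cdh5 and Tie1. Mesothelium had 5 of 10, among them Krt19, which the gastric list also holds, Bnc1 (1.09 kb) and Wt1 (0.625 kb), and none at Lrrn4 and Upk1b, while the replicate 1 list had 8 of 10. Macrophages and leukocytes had 6 of 12, with 1.55 kb at Cd68, 1.17 kb at Lyz2 and 0.703 kb at Tyrobp, and none at Ptprc and Csf1r. The erythroid list had 5 of 14, with 1.91 kb at Tal1, 1.53 kb at Klf1 and 0.719 kb at Nfe2, and none at Hba-a1 and Hba-a2, near-identical copies to which reads are hard to assign. None of these 6 lists passed Fisher's exact test against other genes, with adjusted p of 1.00 for enteric neurons and glia, 0.380 for interstitial cells of Cajal, 0.169 for endothelium, 0.803 for mesothelium, 0.803 for macrophages and 0.246 for the erythroid list. In a single replicate the endothelial list passed, with an odds ratio of 3.78 without replicate 1 and 6.18 without replicate 2. Among peaks with a fold of at least 4 the erythroid (odds ratio 0.116) and macrophage lists (0.136) passed as lower than other genes.

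Genes of the liver, lung and thyroid, central nervous system, germ line and eye were mostly without the mark. Liver genes had a peak at 2 of 14, Trf (0.370 kb) and Ttr (0.293 kb), and none at Alb and Afp (4 of 14 in the replicate 1 list and 3 in the replicate 2 list, with an odds ratio of 0.294 without replicate 2), and the lung and thyroid list at 2 of 12, Etv5 (2.76 kb) and Ager (2.06 kb), and none at Nkx2-1 and Sftpc. Of the forebrain and spinal cord list 3 of 16 had a peak, Dlx1 (2.14 kb), Mnx1 (1.25 kb) and Dlx2 (0.489 kb), and none was found at Foxg1 and Emx1. Of the germ line list only Dazl (0.637 kb) had a peak among 15 genes, without Ddx4 and Sycp1, and of the crystallin and retina list only Opn1sw (1.43 kb) among 16, without Cryaa and Cryba1, with 2 of 16 in the replicate 2 list. These 5 lists were below all other genes, with odds ratios of 0.159 for liver (adjusted exact p = 0.00548), 0.189 for lung and thyroid (adjusted p = 0.0172), 0.206 for forebrain and spinal cord (adjusted p = 0.00982), 0.0820 for germ line (adjusted p = 0.000470) and 0.0767 for crystallin and retina (adjusted p = 0.000265). Against CpG-matched lists the forebrain and spinal cord (median of matched lists 68.8%) and germ line lists (46.7%) still passed, and the liver, lung and thyroid, and retina lists did not, with adjusted permutation p of 0.460, 0.140 and 0.183. A window of 2500 bp around the start site also ended the call for lung and thyroid (odds ratio 0.273).

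The lists of skeletal muscle, heart and kidney did not pass. Skeletal muscle genes had a peak at 4 of 14, with 3.68 kb at Tnni2, 2.92 kb at Mylpf and 1.44 kb at Actn3 and none at Myod1 and Myf5 (odds ratio 0.340, adjusted p = 0.0974 by Fisher's exact test). Heart genes had 4 of 14, with 2.17 kb at Myl3, 1.25 kb at Myh7 and 0.383 kb at Tnnt2 and none at Myh6 and Nppa (odds ratio 0.340, adjusted p = 0.0974, exact). Kidney genes had 4 of 12, with 3.64 kb at Osr1, 1.83 kb at Nphs1 and 1.72 kb at Slc34a1 and none at Pax2 and Six1 (odds ratio 0.420, adjusted p = 0.216, exact). All 3 lists passed as lower in some settings, the heart list without replicate 1 (odds ratio 0.230) and with a fold of at least 4 (0.116), the skeletal muscle list without replicate 2 (0.294), and the kidney list without replicate 2 (0.252) and with the outermost start site only (0.116). The list of pancreas and spleen neighbours had a peak at 9 of 14 genes and did not pass against all other genes (odds ratio 1.37, adjusted exact p = 0.668). Its longest stretches were at Cpa1, a carboxypeptidase of acinar cells (5.14 kb), Nr5a2 (2.52 kb) and Pdx1, a homeobox gene of pancreas, duodenum and distal stomach (1.87 kb, but 4.26 kb in replicate 1 and 0.185 kb in replicate 2), and Prss1 and Ins1 had no peak.

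The longest acetylated stretches lay over anterior and middle Hoxa and Hoxb genes. Of the 25 anterior and middle HOX genes 18 had a replicated promoter peak, in stretches of closely spaced peaks with a median of 51.8 kb, or 55.7 kb in replicate 1 and 27.6 kb in replicate 2. A stretch on chromosome 11 (96298900 to 96355364, 56.5 kb, 11 peaks) ran over the promoters of Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and another on chromosome 6 (52158400 to 52210160, 51.8 kb, 21 peaks) over those of Hoxa1 to Hoxa6 and 5730596B20Rik. Each gene counted the whole stretch that it shares, so the median of the list is the length of the Hoxa stretch. The other 7 genes, Hoxb1, Hoxb9, Hoxc8, Hoxc9, Hoxd1, Hoxd3 and Hoxd4, had no replicated promoter peak, and of the 4 listed Hoxd genes only Hoxd8 had one. Of the limb and posterior HOX list 1 of 16 genes had a peak, and that was Pitx1, so none of the posterior HOX genes of the list, such as Hoxa9 or Hoxa10, had one. By Fisher's exact test the posterior list was below other genes (odds ratio 0.0767, adjusted p = 0.000265), and also below lists matched on promoter CpG, in which the median share was 81.2% (adjusted p = 0.00145). The share of anterior and middle HOX genes did not pass (odds ratio 1.96, adjusted exact p = 0.169), but did in replicate 2 alone (odds ratio 3.62 without replicate 1). The difference between the 2 HOX lists was not tested itself.

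**Figure D3:**
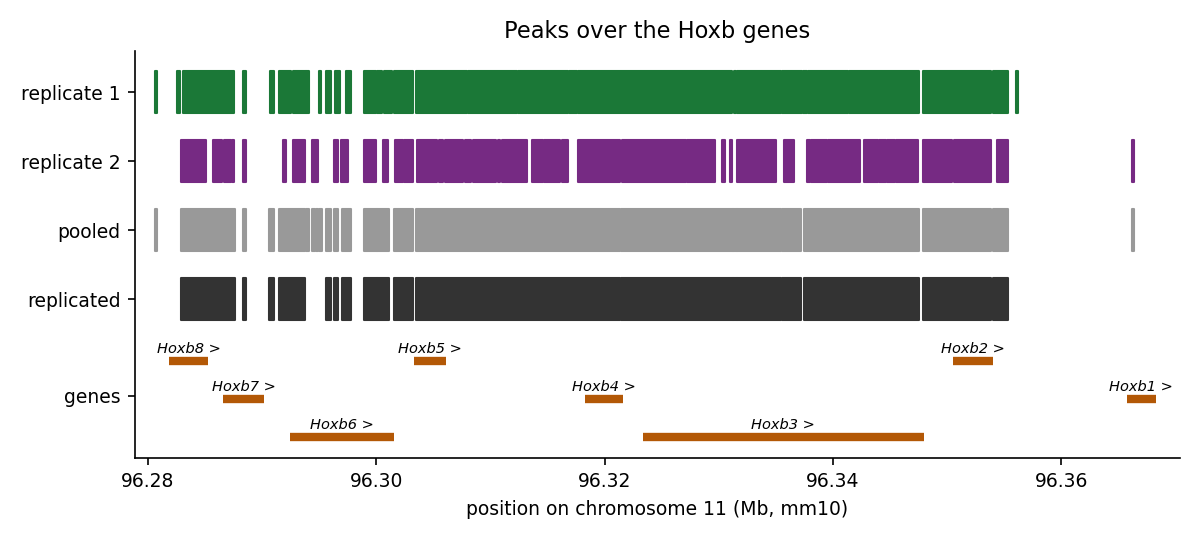
Map of the Hoxb genes on chromosome 11 (horizontal axis, position in Mb on mm10), with the peaks of the replicate 1, replicate 2, pooled and replicated lists drawn to scale as bars in separate tracks above the gene spans. The replicated peaks form a stretch of 56.5 kb from 96298900 to 96355364 that starts inside Hoxb6, covers Hoxb5 to Hoxb2 and stops short of Hoxb1.

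Signalling, growth and imprinted genes were compared in the same way. The retinoic acid and hedgehog list had a peak at 15 of 18 genes, with long stretches at the receptor genes Rara (12.9 kb), Ptch1 (12.8 kb) and Rarg (9.35 kb), and none at Aldh1a2, which makes retinoic acid, and Cyp26a1, which degrades it (odds ratio 3.52, adjusted p = 0.0349 by Fisher's exact test). This call ended with CpG-matched lists (adjusted permutation p = 0.266) and at 4 other settings, with odds ratios of 2.19 to 3.33. The list of WNT and BMP antagonists and targets had 15 of 22, led by the SMAD inhibitor Smad7 (26.7 kb), Id3 (10.3 kb) and Id1 (9.46 kb), without Lef1 and Tcf7, and did not pass (odds ratio 1.64, adjusted exact p = 0.365), except in replicate 2 alone (odds ratio 3.11 without replicate 1). All 18 proliferation genes had a peak, with 7.95 kb at Ccnd2, 5.05 kb at Ccnd1 and 3.56 kb at Rrm2 (odds ratio 29.4, adjusted exact p = 0.000265). All 22 ribosomal protein genes had a peak too, with 10.3 kb at Rpl18, 8.96 kb at Rps11 and 7.14 kb at Rpl10a (odds ratio 35.8, adjusted exact p = 8.82e-05). With a peak at every gene, the odds ratios of the proliferation and ribosomal lists depend on the added constant and on list length. Among imprinted genes 12 of 13 had a peak, with 10.3 kb at Grb10, 7.48 kb at the growth factor gene Igf2 and 5.56 kb at Mest, and none at Ndn (odds ratio 6.62, adjusted exact p = 0.0190). Against CpG-matched lists the ribosomal (adjusted permutation p = 0.0225) and imprinted lists (adjusted p = 0.00828) passed and the proliferation list did not (adjusted p = 0.137). With only the outermost start site of each gene the imprinted list no longer passed (odds ratio 1.38).

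In all, 8 lists were above and 7 below other genes, and 5 and 3 of the 29 lists were so against CpG-matched lists.

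The acetylated stretch at a promoter was longer for the gastric, muscle and matrix lists than for other genes. The median over all genes with a peak was 1.57 kb, and the 99th percentile was 9.98 kb. It was 4.29 kb for the gastric epithelium (6.40 kb in replicate 1 and 3.69 kb in replicate 2), 3.76 kb for the gastric mesenchyme (4.84 and 3.41 kb), 4.11 kb for smooth muscle (4.06 and 3.61 kb) and 3.53 kb for fibroblasts and matrix (4.05 and 3.10 kb). The retinoic acid and hedgehog list had a median of 3.61 kb, imprinted genes 3.44 kb (4.32 and 2.91 kb) and the squamous forestomach 2.90 kb. Proliferation genes had a median of 1.66 kb and ribosomal protein genes 2.05 kb. Endothelial genes had short stretches, with a median of 0.514 kb (1.12 and 0.559 kb), as had the liver genes Trf and Ttr (0.332 kb, with medians of the same genes of 0.984 kb in replicate 1 and 0.257 kb in replicate 2).

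The medians were compared by a permutation test with those of 10000 random lists of the same size among genes with a promoter peak. The permutation p was 0.0002, the smallest that this number allows, for the gastric epithelium, gastric mesenchyme, smooth muscle and anterior and middle HOX lists (adjusted p = 0.00145). Fibroblasts (adjusted permutation p = 0.00193), retinoic acid and hedgehog signalling (adjusted p = 0.00331), imprinted genes (adjusted p = 0.00725), the squamous forestomach (adjusted p = 0.0290) and the posterior HOX list, here Pitx1 alone, also had longer stretches. Endothelium (adjusted permutation p = 0.00193) and liver had shorter ones, so 9 lists were longer and 2 shorter, and random lists matched on promoter CpG gave the same counts. The lists of proliferation (adjusted permutation p = 0.833), ribosomal proteins (adjusted p = 0.148), interstitial cells of Cajal (median 3.04 kb, adjusted p = 0.0912) and WNT and BMP (2.35 kb, adjusted p = 0.0975) did not pass. When peaks were joined over gaps of at most 3 kb, 11 lists in place of 9 passed as longer. Without replicate 2 the squamous forestomach (percentile 94.5), endothelium (16.2) and liver (8.75) lists no longer passed, and without replicate 1 liver did not (3.15). The liver call also ended with a fold of at least 4, and the imprinted call with only the outermost start site of each gene. With the longest single peak in place of joined peaks, the gastric epithelium (percentile 98.5), gastric mesenchyme (93.0), squamous forestomach (82.3), posterior HOX (86.5) and imprinted lists (91.0) did not pass after adjustment.

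**Figure D4:**
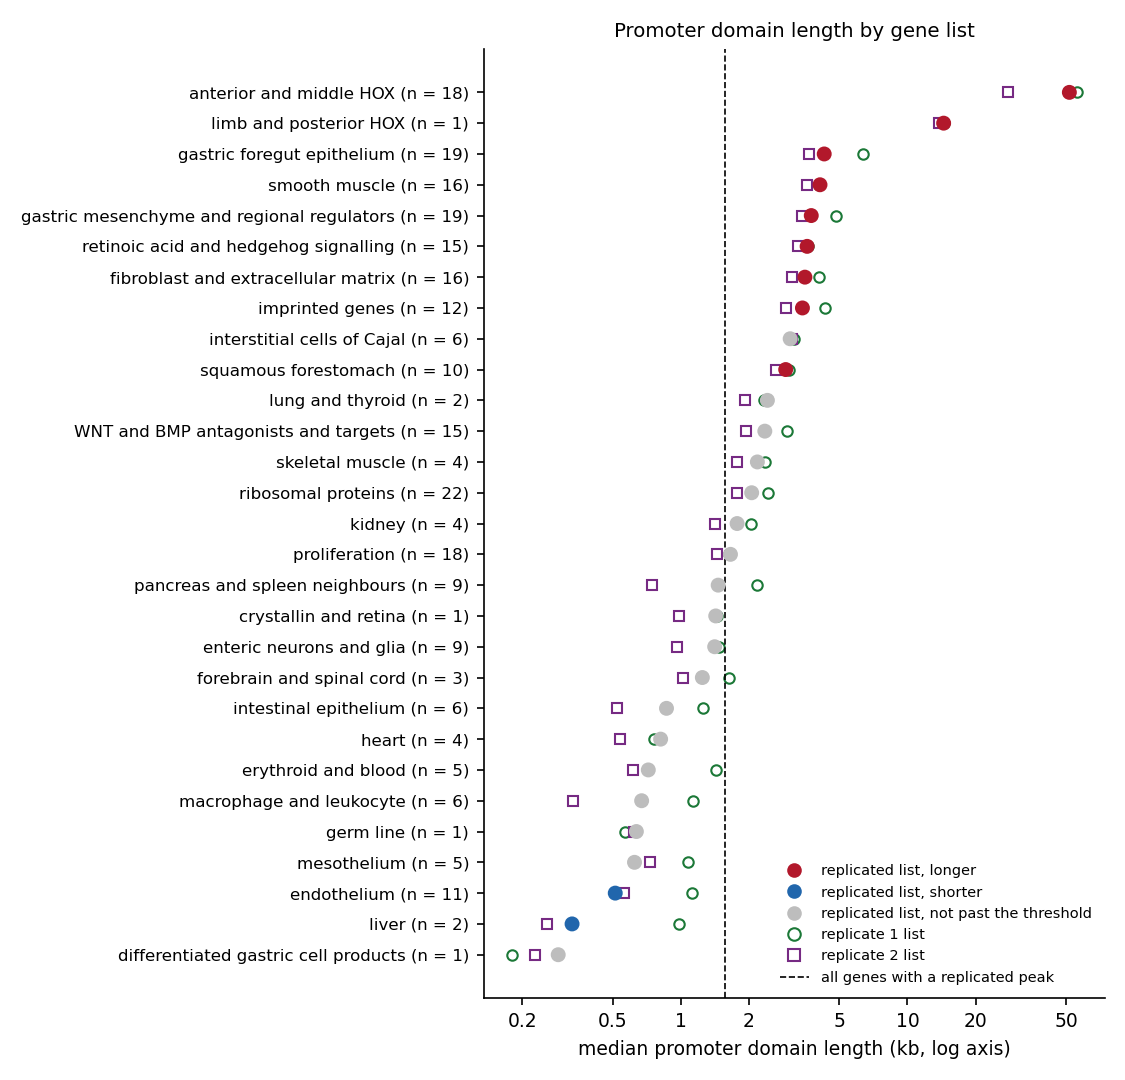
Median length of the acetylated stretch at promoters with a peak (horizontal axis, kb, log axis) for each gene list, with filled points for the replicated list coloured by the test against random lists, open circles and squares for the replicate 1 and replicate 2 lists, and a dashed line at the median of all genes with a replicated peak. Open symbols cover the same genes as the filled points. In the replicated list the median of the gastric epithelium is 4.29 kb and that of endothelium 0.514 kb, against 1.57 kb for all genes with a peak.

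Among the 20 longest stretches, the Hoxb and Hoxa stretches were followed by Smad7 (chromosome 18, 75366232 to 75392941, 26.7 kb), although each replicate alone gave at most 15.05 kb there, and Cirbp with Midn (23.98 kb). Lsp1 (21.4 kb), Meis2 (20.7 kb), Lasp1 (20.5 kb, but 9.90 kb in replicate 2), Bahcc1 (20.4 kb) and Col1a1 (chromosome 11, 94932267 to 94952456, 20.2 kb) followed. Meis1 (18.5 kb), like Meis2 a partner of HOX proteins, Irf2bpl (18.3 kb), Zmynd8 (17.9 kb) and Foxf1 (chromosome 8, 121070893 to 121087109, 16.2 kb) were next. Krt15 and Krt19 shared a stretch (chromosome 11, 100132581 to 100148511, 15.9 kb), as long as that of Sema3f (15.9 kb). The last were Foxa1 (chromosome 12, 57534342 to 57550027, 15.7 kb, but 8.52 kb in replicate 2), the thyroid hormone receptor gene Thra (15.7 kb), Zfhx3 (15.6 kb), Hic1 (15.02 kb, but 9.87 kb in replicate 2) and Sept9 (14.8 kb, but 6.72 kb in replicate 2).

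Away from promoters, the largest cluster of replicated peaks lay on chromosome 12 (79878608 to 80107536), 5.46 kb from Zfp36l1, which encodes an RNA-binding protein that destabilises AU-rich transcripts, and its 62 peaks covered 86.2 kb (88.2 kb in replicate 1 and 68.9 kb in replicate 2). The next overlapped Gtf2e2 and Rbpms (62.2 kb covered, chromosome 8), Cstad (57.8 kb, chromosome 2), Lsp1, Mrpl23 and Tnnt3 (50.8 kb, chromosome 7), and Ddc (47.2 kb, chromosome 11). RBPMS is an RNA-binding protein of smooth muscle. Further clusters overlapped Rad51b (46.0 kb), Rxra, a partner of the retinoic acid receptors (44.2 kb), Il17b (43.6 kb), and Acvr1b, Acvrl1, Ankrd33, Grasp and Nr4a1 (41.4 kb), and the last lay 106.4 kb from Haao (39.9 kb). When distal peaks were joined over gaps of at most 12 kb they formed 17423 clusters, of which 8331 were single peaks and 420 had at least 10 kb covered and held 21.3% of the distal covered length. That count was 192 with gaps of at most 5 kb and 177 with peaks of a fold of at least 4. Whether distal peaks lay closer together than chance was not tested, and the nearest or overlapped gene is a position and not a target.

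Binding motifs of several families of transcription factors were more frequent in the distal peaks than in matched sequence. The E-box CAGCTG of basic helix-loop-helix factors was in 33.6% of the 500 bp windows centred on the peaks and 26.2% of windows with like GC content outside peaks (odds ratio 1.42, adjusted exact p = 1.36e-127). The forkhead motif TGTTTAC was in 8.49% and 5.63% (odds ratio 1.56, adjusted exact p = 2.87e-62), the AP-1 motif TGASTCA in 11.6% and 8.21% (1.46, adjusted p = 2.87e-62) and the TEAD motif in 14.96% and 12.1% (1.27). Motifs of muscle genes were more frequent too, with MEF2 in 1.13% and 0.515% (2.21) and the CArG box of SRF in 2.78% and 2.36% (1.18). So were those of the endodermal factors HNF4 (0.965% and 0.632%, 1.53), GATA (11.0% and 9.83%, 1.14) and CDX (6.23% and 5.40%, 1.16). NFI (odds ratio 3.11, 95% interval 1.84 to 5.25), ETS (1.86), MITF (1.39) and RUNX (1.09) completed the 13 of 19 motifs that were more frequent by Fisher's exact test, and 0 were less frequent. SOX (1.02, adjusted exact p = 0.268), CTCF (0.893, adjusted p = 0.117), HNF1 (adjusted p = 0.0848), the E-box of neurons and pancreas (0.988, adjusted p = 0.383), NRF1 (adjusted p = 0.305) and REST (adjusted p = 0.150) did not pass. The same motifs read in reverse, a control of equal base composition but not always of equal CpG content, also departed from 1 in both directions at an unadjusted exact p under 0.05, with odds ratios of 1.15 for the forkhead, 1.11 for SOX, 1.09 for AP-1 and 1.19 for MITF, and of 0.859 for the E-box of neurons, 0.913 for CDX, 0.936 for GATA and 0.936 for RUNX. For 14 of the 19 motifs the odds ratio was above that of its reverse, and among the 13 that passed the exception was NFI, whose reverse was in 0 of the control windows. Reversal created or removed a CpG in CAGCTG, NFI, ETS and MITF, among others, so this count rests in part on unlike controls. The reverse of CAGCTG, for example, was in 0.925% of peaks and 0.914% of control windows. Windows 5 kb downstream of each peak were also used as controls, for 35401 peaks, and were not matched in GC content. With these the direction turned for GATA (0.982), and SOX (0.921), CDX (0.910) and RUNX (0.807) passed as less frequent in the peaks. The CArG call ended without replicate 2 (1.01) and the RUNX call without replicate 1 (1.03). In the middle 200 bp of the peaks the CArG (1.06), RUNX (1.01) and ETS (1.04) calls ended, and with a fold of at least 4 the RUNX (1.06) and ETS (1.48) calls did.

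Across chromosomes the X stood apart. It had 4.74 replicated peaks per Mb, while the autosomes had from 17.6 (chromosome 14) to 40.3 (chromosome 11). The replicate lists had 9.12 and 5.88 peaks per Mb on the X. Of the X-linked protein-coding genes 35.5% (337 of 948) had a replicated promoter peak, and away from promoters the X had 2.12 peaks per Mb against 13.0 to 28.5 on autosomes. The Y chromosome had 2 replicated peaks, at the promoters of Uty and Ddx3y, and the labels give pools of both sexes. No test between replicates was possible for these densities, and both replicates showed the X lowest among the chromosomes other than Y.

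**Figure D5:**
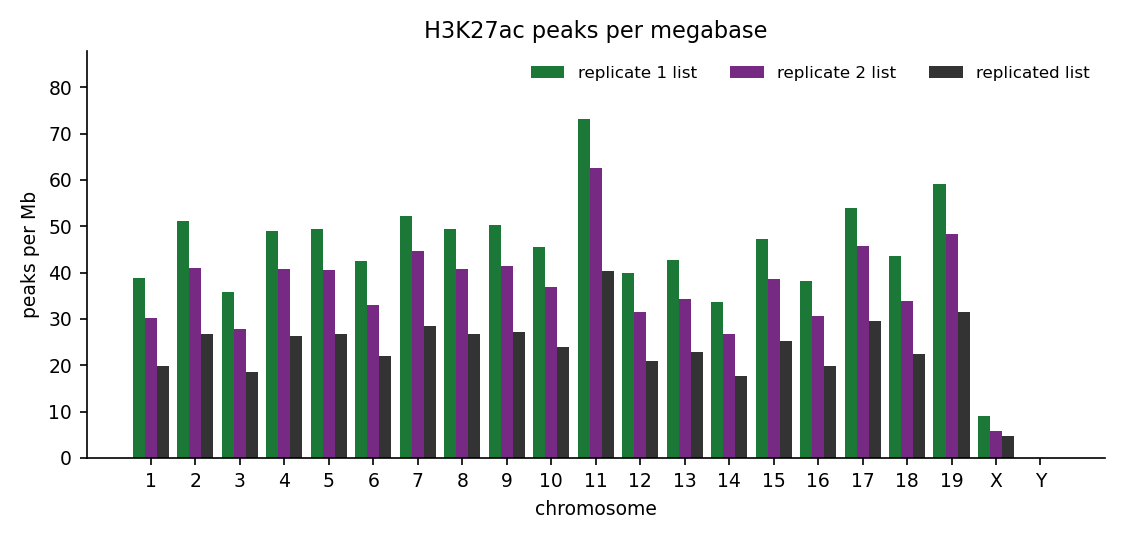
Peaks per Mb (vertical axis) on each chromosome (horizontal axis), with bars side by side for the replicate 1, replicate 2 and replicated lists. The X chromosome has 4.74 replicated peaks per Mb, and the autosomes range from 17.6 to 40.3.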

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

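No test was run on the values of this part, which were looked at because they lie in data that the comparisons did not use. Peaks on sequence that is not placed on an assembled chromosome were present in every list, with 12 in replicate 1, 7 in replicate 2, 10 in the pooled list and 7 in the replicated list. Any such peak is above a count of 0, and no control sample was analysed that would give the number expected without the antibody. No biological or technical explanation was tested for them.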

How the results depend on the processing

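Leaving out the X and Y chromosomes and counting each domain once per list were chosen after the results were seen, and all other settings before. No paired analysis was possible because there was 1 group. Sequencing depth is unknown, and the share of peaks found in both replicates depends on where a list ends, as the values below show. The number of genes with a promoter peak (10705 to 12999) and of motifs past the threshold (11 to 17) stayed within 1.5 times the reported value in every setting run for them. The motifs that passed as less frequent, 0 in the reported comparison, were SOX, CDX and RUNX with controls 5 kb downstream, CTCF in the middle 200 bp (0.773), the E-box of neurons in windows of 1000 bp (0.953) and without replicate 2 (0.960), and REST with a fold of at least 4 (0.219).

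The share of replicate 1 peaks found in replicate 2 was 49.6% with an overlap of 1 bp, 29.5% with 50% of both peaks, 45.1% with q of at most 0.01, 64.6% with a fold of at least 4, 77.1% among the 20000 strongest peaks and 52.6% with peaks joined over 1 kb. The share of replicate 2 peaks found in replicate 1 was, in the same order, 71.0%, 36.4%, 75.5%, 84.2%, 85.8% and 63.5%. The Jaccard index was 0.478 with q of at most 0.01, 0.554 with a fold of at least 4, 0.596 among the strongest peaks and 0.505 with peaks joined. Of the pooled peaks 61.3% were kept with q of at most 0.01 and 99.7% with a fold of at least 4. The share of replicated peaks at promoters was 32.98% with windows of 2500 bp, 22.9% with the outermost start site, 44.2% with a fold of at least 4, and 19.2 to 23.0% in a single replicate. A wider window takes in more peaks and a single start site per gene fewer by construction, and for the fold the cause was not tested. Large distal clusters numbered 192 with gaps of 5 kb and 177 with a fold of at least 4, for which fewer peaks are joined, 574 with gaps of 20 kb, and 284 to 568 in a single replicate.

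Of the lists, 8 in place of 15 passed by promoter peak against CpG-matched lists, and 13 to 19 in every other setting. By domain length 6 in place of 11 passed without joining, and 10 to 13 in every other setting, with 10 to 12 in a single replicate. Of the 15 calls by promoter peak, all were kept with windows of 500 bp, with q of at most 0.01 and without replicate 1. Of the 11 calls by domain length, all were kept with gaps of 3 kb, with CpG-matched lists and with each domain counted once. Of the 97 named genes with a stretch, 31 had one more than 1.5 times longer or shorter in a replicate list alone. Beside those given in the report, replicate 1 had longer ones at Cd68 (5.45 kb), Eng (3.30 kb), Hand2 (17.4 kb), Nfe2 (1.37 kb), Nr5a2 (3.92 kb), Rara (23.9 kb), Tal1 (4.38 kb), Trf (0.744 kb) and Ttr (1.22 kb) and shorter ones at Gkn3 (0.180 kb) and Tnnt2 (0.235 kb). Replicate 2 had shorter ones at Actn3 (0.886 kb), Ager (1.23 kb), Dlx1 (1.02 kb), Dlx2 (0.229 kb), Egfl7 (2.46 kb), Eng (0.933 kb), Hoxa1 (3.04 kb), Hoxb2 (17.6 kb), Lyz2 (0.339 kb), Myh7 (0.744 kb), Nr5a2 (1.54 kb), Rrm2 (2.14 kb), Ttr (0.175 kb), Tyrobp (0.203 kb) and Vil1 (0.503 kb). Over all settings 203 of 388 values of single genes moved by more than 1 SD of the replicates.

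Some lists changed side of the middle value, and none of these was past the threshold in the reported comparison. Odds ratios by promoter peak turned for enteric neurons (0.941 with windows of 2500 bp, 0.826 with a fold of at least 4, 0.957 without replicate 1), endothelium (0.448) and pancreas and spleen (0.8004) with a fold of at least 4, macrophages (1.43 without replicate 1 and 1.30 without replicate 2) and mesothelium (2.33 without replicate 2, but 0.756 without replicate 1). The percentiles among CpG-matched lists lay on the other side for intestinal epithelium (85.6), enteric neurons (16.2), erythroid cells (79.0), macrophages (93.2) and WNT and BMP (5.47). Percentiles by domain length turned for lung and thyroid (32.4), skeletal muscle (28.2), kidney (40.2) and proliferation (7.71) without joining, for pancreas and spleen (55.4) and proliferation (44.1) with gaps of 3 kb, for mesothelium (84.7), heart (54.8), kidney (10.1) and proliferation (8.11) with a fold of at least 4, and without replicate 2 for pancreas and spleen (84.7, but 4.29 without replicate 1) and forebrain (50.4, but 27.9 without replicate 1). The cause was not tested.

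Among motifs the odds ratio turned with controls 5 kb downstream, not matched in GC content, for GATA (0.982), SOX (0.921), CDX (0.910), CTCF (1.15), RUNX (0.807) and the E-box of neurons (1.09). It turned in the middle 200 bp for SOX (0.964) and NRF1 (0.931), in windows of 1000 bp for CTCF (1.28), without replicate 1 for CTCF (1.05) and without replicate 2 for CTCF (1.03) and REST (1.02). Of these GATA, CDX and RUNX were past the threshold in the reported comparison, and the cause was not tested.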

Other observations

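All tests of gene families and of lists near clusters, the depth ratio, the CpG test of the pancreas list and the values for non-coding genes were chosen after the results were seen, and the other tests before. Families of regulators differed in how many members carried the mark, in comparisons of 42 families with random lists of equal promoter CpG (permutation tests, adjusted over the families). ETS factors had a replicated promoter peak at 20 of 23 genes, without Etv2, Spib and Spic, and the median of matched lists was 60.9% (adjusted permutation p = 0.00945). Subunits of respiratory complex I had 35 of 36 (adjusted permutation p = 0.0042), subunits of the proteasome 35 of 39 and zinc finger genes named Zfp 301 of 394, and these 4 families were the only ones above matched lists. Of the 14 families below, T-box factors had 3 of 15 (Tbx3, Tbx2 and Tbx6), LIM homeobox factors 2 of 12 (Isl1 and Isl2), PAX factors 1 of 9 (Pax9), NKX factors 6 of 14 and FOX factors 24 of 44, where matched lists had medians of 60, 66.7, 66.7, 78.6 and 77.3%. WNT ligands had 5 of 19 (Wnt5a with a stretch of 3.42 kb, Wnt4 with 2.51 kb, Wnt5b, Wnt9a and Wnt2b) and BMP and GDF ligands 6 of 21, led by Bmp7 (7.46 kb) and Bmp4 (5.36 kb), but 10 of 21 in the replicate 1 list. A peak was present at 9 of 10 Frizzled receptor genes, 8 of 8 SMAD genes and 8 of 9 genes of NOTCH receptors and ligands, and none of these families passed against matched lists. Protocadherins (9 of 68), potassium channels (33 of 94), chemokines (4 of 31), olfactory receptors (1 of 1092, Olfr56), vomeronasal receptors (2 of 326), defensins (0 of 64) and keratin-associated proteins (0 of 57) were also below. In the replicate 1 and replicate 2 lists the counts were 9 and 4 for chemokines, 5 and 8 for olfactory receptors and 1 and 2 for keratin-associated proteins, and the test against matched lists was not run on them.

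Other families had long promoter domains. The NFI factors, whose motif was rare but more frequent in distal peaks than in matched sequence, had a median of 9.13 kb (Nfic 10.2, Nfib 9.96, Nfia 8.29 and Nfix 6.32 kb), the AP-1 factors 5.88 kb (Junb 12.6 kb), keratins with a peak 4.01 kb, Frizzled receptors 3.59 kb (Fzd2 9.37 and Fzd7 8.52 kb) and KLF factors 3.56 kb (Klf3 11.4 and Klf5 8.28 kb). These and the SOX, FOX, ETS and MEIS families were the 9 of 40 families with longer domains than random lists, and Zfp genes (1.28 kb), NKX factors (0.277 kb) and proteasome genes (1.06 kb) had shorter ones. Among non-coding genes, Carmn, known from smooth muscle, had a stretch of 23.5 kb in replicate 1 and 23.1 kb in replicate 2, inside the large cluster at Il17b. H19 had 22.2 and 14.5 kb, Meg3 had 1.78 and 2.06 kb, Fendrr shared the stretch of Foxf1, Malat1 had 7.95 and 20.3 kb, and Hotair and Hottip, which lie among posterior HOX genes, had no peak. Large distal clusters lay within 50 kb of the start of 3.75% of the genes outside the imprinted list and of 7 of 13 imprinted genes (53.8%, among them Igf2, Dlk1 and Grb10) and of 6 of 14 genes of the squamous forestomach (Krt14, Krt15, Krt4, Krt13, Pitx1 and Grhl3). They also lay near 6 of 20 genes of the gastric epithelium (Gata4, Cdh1, Krt8, Krt18, Krt19 and Elf3) and 5 of 20 of the gastric mesenchyme (Foxf1, Foxl1, Ptch1, Nr2f2 and Hand2). They were also near 7 of 25 anterior and middle HOX genes (all Hoxa), 5 of 16 of the limb and posterior HOX list (Hoxa9, Hoxa10, Hoxa11, Hoxa13 and Pitx1), 5 of 22 of the WNT and BMP list and 4 of 16 of the crystallin and retina list (Crybb2, Crybb3, Rho and Gnat1), so being near a cluster did not single out genes of the stomach. Adjusted exact p by Fisher's test was 4.38e-06 for the imprinted list, 9.6e-05 for the squamous list, 0.000275 for anterior HOX, 0.00051 for the epithelium, 0.00136 for posterior HOX, 0.00355 for the mesenchyme, 0.00486 for WNT and BMP and 0.00928 for the retina list, and these were the 8 of 29 lists that passed. Several of these genes neighbour each other in the keratin and HOX clusters, so they are not independent. Distal peaks also include the outer peaks of long promoter domains. The cluster at Hoxa (chromosome 6, 52161747 to 52211717), for example, overlies the Hoxa stretch (52158400 to 52210160). Lists with long promoter domains can thus lie near clusters in part by construction.

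Replicate 1 had more peaks than replicate 2. At an authors' fold of 8 to 12, the median −log10 p was 33.6 over 4899 peaks of replicate 1 and 28.0 over 4104 peaks of replicate 2, a ratio of 1.1999, which is consistent with a greater depth of replicate 1 or of its control. A different make-up of the pools was tested by the 25% of replicate 1 peaks with the highest fold, of which 7.33% had no replicate 2 peak (6.12% with an overlap of 1 bp), more than the 5% set beforehand. That value came from the weaker of these peaks, since 99.9% of the decile with the highest fold, 93.3% of the next and 71.5% of the one after were found in replicate 2, and 1.82% of the corresponding 25% of replicate 2 peaks had no replicate 1 peak, so it may also follow from depth, and both explanations stay open. The embryos of the pools themselves, which the labels do not describe further, are an untested biological source.

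The X chromosome had few replicated peaks per Mb. Of its protein-coding genes 35.5% had a replicated promoter peak, below the range of 45.0 to 50.3% that held 95% of autosomal lists with equal promoter CpG. This argues against promoter CpG, as taken at the outermost start site, as the whole source. The share met the bound set beforehand against gene content, but the lists were not matched on the number of start sites or on which kinds of genes the X holds. The test cannot decide on gene content, which stays open. Outside repeats it had 4.16 distal peaks per Mb, while the lowest autosome had 20.5, which argues against repeats. A single active X per cell could lower the enrichment of X-linked peaks. The ratio of median folds of 337 X-linked to matched autosomal promoters was 0.857 (95% range over random draws 0.752 to 0.969), between the bounds set beforehand, so the value decided neither way. Only promoters with a replicated peak entered. X-linked promoters too weak for a peak were left out, so the ratio can understate a lowering on the X. The labels give both sexes in each pool but not their share, which keeps a single active X open, and no biological explanation was tested against it.

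The list of pancreas and spleen neighbours had a promoter peak at 9 of 14 genes, among them Pdx1, Ptf1a, Nkx6-1 and Cpa1. Pancreatic tissue in the dissected stomachs could bring such peaks, and 24 other genes of acinar enzymes were listed to test it, of which 20.8% had a replicated promoter peak (95% Wilson interval 9.24 to 40.5%), as in the median of matched lists (20.8%), while the replicate 1 list had a peak at 9 of the 24 and the replicate 2 list at 6. Cpa2 (6.54 kb), Clps (6.41 kb), Rnase1 (1.78 kb), Pnliprp1 (1.76 kb) and Pnliprp2 (0.791 kb) had a peak, and Cpb1, Cel, Pnlip, Try4 and Amy2a5 did not. Cpa2 and Cpa1 lie near each other on chromosome 6, so their peaks are not independent. Large distal clusters overlapped Cpa2 (30524976 to 30577481), Cpa1 (30617997 to 30683761) and the nearby imprinted gene Mest (30696398 to 30730369). Whether the peaks at Cpa1 and Cpa2 belong to this neighbourhood was not tested. The value met the bound set against this source but not by more than its spread, a requirement added after the value was seen, so this source stays open, also since how many of these genes the stomach itself expresses is not in the files. Promoter CpG content remains open too, as the list lay at the percentile of 94.3 among CpG-matched lists, between the bounds of its test.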
